A study of Homo sapiens with 2 samples.

How the data were processed

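Total RNA of T47D cells carrying ESR1 Y537S and transfected with 25 nM control siRNA was sequenced as stranded, ribosomal RNA-depleted libraries, per the labels' protocols. The group and the replicate numbers were taken from the sample labels, which gave 1 group of 2 libraries. The columns of the table were matched to the samples by cell line, receptor residue and replicate number; the column names do not repeat the siRNA, so this match rests on those 3 parts of the name. Another 8 columns of per-sample values, which match no sample described here, were not used in any step. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. The exact p-values set these 2 libraries against counting error and do not measure that spread.

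Per the file headers, the authors counted reads per gene with featureCounts 2.0.2 over exons of GENCODE release 19, in whole-number counts with no normalization. The recorded call set neither a strand option nor a paired-end option, nor options for multimapping or overlapping reads. Per the submitters' processing notes, HISAT2 was used, and the build was hg19 (GRCh37); a HISAT2 version is not given in the sources used here. Counting without strand means that reads of a gene and of an overlapping antisense gene cannot be told apart. By the counter's default, reads that fit several places or several genes are then not counted, so genes with near-identical copies or overlapping rows can be underestimated, and mates of a pair, if the reads were paired, were counted one by one. Gene length in the deposited table is the summed exon length. Per the labels' protocols synthetic spike-in RNA was added; spike-in reads were not used here.

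From the deposited counts, CPM was computed over the sum of all 57820 genes, and TPM with the deposited lengths over the same genes. Names came from the gene identifier tables supplied with the genome annotation, which matched 52338 identifiers (90.5%); identifiers without a match held 8.80% and 10.5% of the reads. Gene types came from GENCODE release 29, matched by identifier, and its coordinates were not used. Of 369 entries in the 21 gene lists 362 were matched by symbol. PECAM1, UHRF1, H3C2, RN7SK, RN7SL1, RN7SL2 and RPPH1 were not. The 7SK RNA was counted under the name 7SK, so RN7SK is missing from its list by symbol alone. Other unmatched entries may also stand under another name or an identifier. Lists, pairs, tests, thresholds and the alternatives were set before the data were examined, except where a choice is said to have been made after seeing the data.

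The total was 41370662 reads in replicate 1 and 37198274 in replicate 2. Counting intervals are exact Poisson 95% intervals of single counts, or exact conditional binomial 95% intervals of a ratio of 2 counts, and the floor for a count of 0 was 3 reads per library. Intervals, floors and exact p-values cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was called detected at 1 CPM or more in both libraries. A list's level was the median over its members of the mean log2(TPM + 0.1), set against 10000 random lists of the same number of protein-coding genes as a percentile, with bounds at 2.5 and 97.5. This describes the libraries and is no test. Random lists were drawn from all protein-coding genes, 60.9% of them detected, so lists of broadly expressed genes tend to rank high. Median levels printed in TPM are the mean ± SD of the 2 libraries' medians. A pair's ratio was called larger than the replicate spread when its interval excluded equality in the same direction in both libraries and its mean exceeded the 95th percentile of absolute replicate differences in the CPM class of the lower gene. That spread compares the same gene between the libraries. It holds no error between different genes, such as that from exon length, so most pairs pass it easily.

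With 1 group, no test between conditions and no split of samples was possible. The 2 libraries were compared gene by gene with an exact two-sided binomial test at the share given by TMM effective library sizes, with Benjamini-Hochberg adjustment. TMM factors and the coefficient of biological variation, from a fit with an intercept alone, came from edgeR 4.0.16. The libraries were kept as 2 replicates, as labelled; the chi-square statistic of 22.9 per gene only shows that they are not repeat counts of 1 library within sampling noise, and mates counted one by one would raise it. On simulated Poisson counts for the 14668 genes of this comparison, with 200 genes changed, the binomial test recovered 64.2% of genes changed 1.25-fold, 76.1% of those changed 1.5-fold and 92.4% of those changed 2-fold, and called 6 of 14468 unchanged genes. The simulated counts hold no spread beyond counting noise, unlike these libraries, so these rates do not carry over to the calls made here.

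Genes named in the text were chosen by a rule set beforehand: the 15 most abundant nuclear protein-coding genes, the 3 highest members of each list and each detected member of lists of other cell types, the genes of the pairs, ESR1 and the KDM4 family, and the 10 genes with the largest replicate difference at 10 CPM or more and an adjusted p under 0.05. List members that were not detected, and a few genes said to be chosen after seeing their values, were named besides, and a few genes that the rule takes are not reported here. Alternatives were detection at 0.5 and 5 CPM, library sizes without the 10 most abundant genes, other gene filters and pseudocounts, DESeq2 1.42.0 size factors and library totals, CPM in place of TPM, TPM over nuclear protein-coding genes, each replicate alone, and 2 added after seeing the data: halved counts and lists without the chromosome 6 block. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.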

Results

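The data were gene-level read counts from total RNA of T47D cells, an established line of human estrogen receptor-positive luminal breast cancer. The cells carried ESR1 Y537S, an exchange in the ligand-binding domain of estrogen receptor alpha that keeps the receptor active without hormone. They were grown in hormone-deprived medium and transfected with 25 nM of a control siRNA. The labels gave 1 group of 2 replicate libraries, so no comparison between conditions was made, and each level below describes this control state. The library of replicate 1 held 41370662 reads on genes and that of replicate 2 held 37198274. At 1 CPM (reads scaled to library size) or more in both libraries, 14176 of 57820 genes were detected, among them 11731 of 19263 protein-coding genes (60.9%). No read fell on 25982 genes in either library. Levels are TPM, scaled to the summed exon length of each gene and to library size, as mean ± SD of the 2 libraries unless another unit is named. A gene with more annotated exon bases thus has a lower TPM for the same reads, so ranks and ratios depend on that length. Coordinates are those of hg19.

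Among protein-coding genes of the nuclear genome, the highest levels belonged to linker histones, ribosomal proteins, cytoskeletal genes and genes of luminal secretory epithelium. The linker histone H1-2 led with 1608 ± 147 TPM (n = 2), followed by RPL7A with 1420.1 ± 86.2 and the luminal keratin KRT19 with 1385 ± 19.6. The constitutive chaperone HSPA8 had 1225 ± 418 TPM, with 1521 in replicate 1 and 929.7 in replicate 2, the widest gap among these 15 genes. RPL8 stood at 1149 ± 62.5, ACTB at 1133 ± 75, the matrix Gla protein gene MGP at 1076 ± 3.6 and the secreted disulfide isomerase family gene AGR2 at 1075 ± 20.3 TPM. Next came the linker histone H1-5 with 1074 ± 117, the actin-binding peptide gene TMSB10 with 1052 ± 17.4, RPS27 with 1044 ± 15.8 and the linker histone H1-4 with 1009.9 ± 71.1 TPM. ATP5F1B, a subunit of mitochondrial ATP synthase, had 943 ± 94.5, TMSB4X 921 ± 19.6 and the core histone H4C3 904 ± 70.5 TPM. Short noncoding RNAs took a large part of the TPM scale: nuclear protein-coding genes made up 29.8% of it in replicate 1 and 26.4% in replicate 2, although they and the mitochondrial protein-coding genes held 82.4% and 80.1% of the reads. On a scale of nuclear protein-coding genes alone, the TPM values would be 3.35 and 3.78 times as high.

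Genes of luminal epithelium ranked above random lists of protein-coding genes in both libraries. Of the 22 luminal genes, 21 were detected, the exception being TFAP2B with 14 and 5 reads in the 2 libraries. Their median level was 67 ± 6.71 TPM, at percentile 100 of 10000 random lists of protein-coding genes, whose medians lay between 0.103 and 9.03 TPM in the middle 95%. KRT19 (ENSG00000171345.9, chromosome 17, 39679869 to 39684560), the prolactin receptor gene PRLR with 602 ± 83.9 and KRT8 with 464 ± 78 TPM were its highest members. The pioneer factor FOXA1 stood at 82.1 ± 0.325, the adhesion gene CDH1 at 85.1 ± 11.1 and KRT18 at 199 ± 22.3 TPM.

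Lists of mesenchymal, fibroblast, immune and endothelial genes had medians below the middle 95% of random lists, and the basal and myoepithelial list lay within that range. Of the 15 basal and myoepithelial genes 8 were detected, led by the cadherin CDH3 with 7.8 ± 1.15, the laminin chain LAMA3 with 4.93 ± 0.568 and TAGLN with 3.29 ± 0.326 TPM. The other detected members were ACTA2 (2.2 ± 0.521), EGFR (1.09 ± 0.225), OXTR (0.56 ± 0.201), MYLK (0.506 ± 0.0495) and NGFR (0.436 ± 0.0127 TPM). The basal keratins KRT5, KRT14 and KRT17 had 2 and 6, 2 and 0 and 0 and 2 reads, and KRT6A and KRT6B had none in either library. The median of this list was 0.423 ± 0.0068 TPM, at percentile 18.2 of random lists. Of 14 mesenchymal genes, FN1 with 10.9 ± 0.555 and TWIST1 with 2.41 ± 0.473 TPM were detected, VIM had 3 and 3 reads, and 8 members had at most 3 reads in each library. The mesenchymal median lay at percentile 0.96 (0.92 to 1.65 from single libraries). Among 10 fibroblast genes COL1A1 was detected with 1.11 ± 0.0783 TPM, and among 9 endothelial genes ESAM with 0.749 ± 0.142 TPM. Of 15 immune genes 2 were detected, among them CSF1R with 0.392 ± 0.0775 TPM. The fibroblast median lay at percentile 0.75 (1.08 to 1.15 from single libraries) and the endothelial median at percentile 0.705 (1.28 to 1.36). For the immune list the percentile was 2.12, below the lower bound of 2.5, but from replicate 2 alone it was 4.56 and with CPM in place of TPM 2.90. For a count of 0 the floor was 3 reads, which was 0.0725 CPM in replicate 1 and 0.0806 CPM in replicate 2.

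Ratios between luminal genes and relatives typical of other lineages spanned 2 to 4 orders of magnitude within each library. KRT8 stood 29500.3-fold above KRT5 in replicate 1, with a 95% counting interval of 8166 to 243599, and 7748-fold above it in replicate 2 (3559.5 to 21114). KRT18 exceeded KRT14 6485-fold in replicate 1 (1795 to 53556). In replicate 2 KRT14 had no reads, and the ratio was 3691 at the floor of 3 reads per library, with a lower 95% bound of 3002. The KRT18 to VIM ratio was 9411 (3219.8 to 45639) and 8035 (2749 to 38966). The epithelial cadherin CDH1 was 543-fold above the neural cadherin CDH2 (log2 ratio 9.08 ± 0.14, SD, n = 2). FOXA2 had no reads in either library, and at that floor FOXA1 was 1893-fold and 1884-fold above it (lower 95% bounds 1539 and 1531). All 5 ratios exceeded the 95th percentile of replicate differences of genes as low as the lower partner. ERBB3 exceeded EGFR 72.5-fold (log2 ratio 6.18 ± 0.27).

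**Figure D1:**
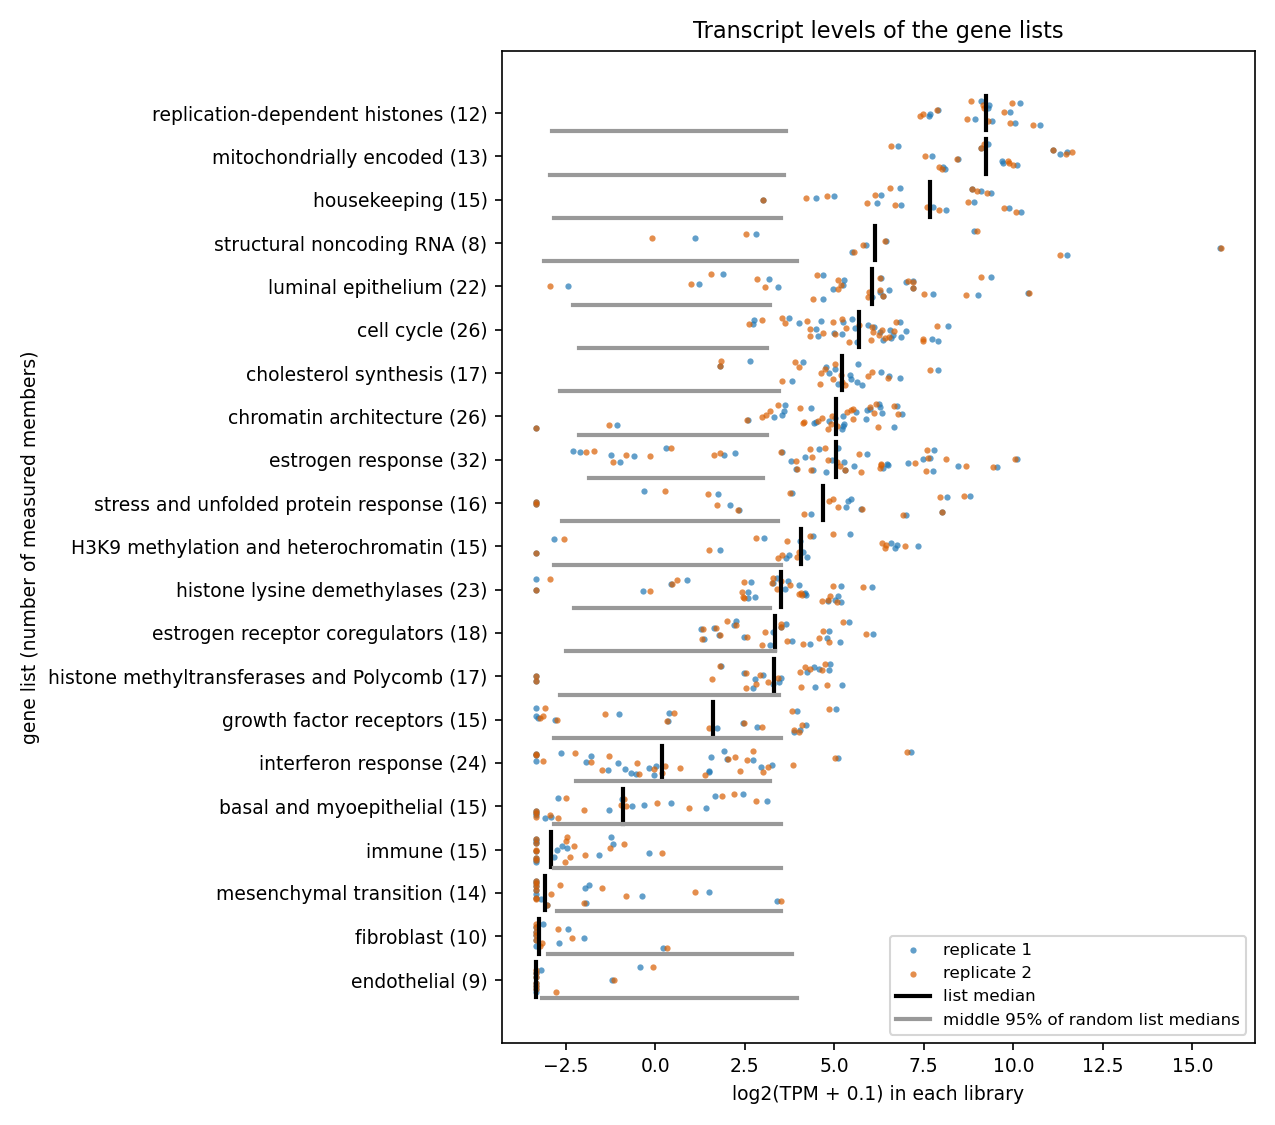
Levels of the members of the 21 gene lists, as log2(TPM + 0.1) on the x axis, with 1 point per gene and library (blue for replicate 1, orange for replicate 2). Black bars mark list medians and grey lines the middle 95% of medians of 10000 random protein-coding lists of the same size; 12 lists lie above that range, 4 below it and 5 within it.

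The estrogen receptor and its target genes were measured next, since the cells carry the Y537S receptor. ESR1 (ENSG00000091831.17, chromosome 6, 151977826 to 152450754) had 25.7 TPM in replicate 1 (95% counting interval 25.2 to 26.2) and 21.2 in replicate 2 (20.7 to 21.7). It stood 76.5-fold above ESR2, the gene of estrogen receptor beta (log2 ratio 6.26 ± 0.02). Of the 32 estrogen response genes 30 were detected, KRT13 and ELOVL2 being the exceptions, and the list median was 31.5 ± 1.04 TPM, at percentile 100 of random lists. AGR2, the stress-linked transcription factor XBP1 with 723 ± 37.8 and the growth factor-binding protein gene IGFBP4 with 378 ± 42.8 TPM led it. The progesterone receptor gene PGR (ENSG00000082175.10, chromosome 11, 100900355 to 101001255), a classical receptor target, had 203 ± 18.4 TPM. The cyclin CCND1 reached 79.6 ± 2.62 TPM, and CCND2 had no reads. The lower 95% counting bounds of the ratio of CCND1 to CCND2 were 4186 in replicate 1 and 3998 in replicate 2. They would be too high if mates of a pair were counted one by one. TFF1, a secreted trefoil peptide gene used as a marker of receptor activity, had 27.4 TPM in replicate 1 and 53.5 in replicate 2.

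The treatment protocol of the series names KDM4C as the target of a knockdown, whose libraries were not analysed here, and the KDM4 family was therefore examined in each control library. These enzymes remove methyl groups from histone H3 lysine 9. KDM4B (ENSG00000127663.10, chromosome 19, 4969125 to 5153606) had 18.2 and 16.6 TPM in replicates 1 and 2, and KDM4A (ENSG00000066135.8, chromosome 1, 44115829 to 44171186) 17.7 and 16.2. KDM4C (ENSG00000107077.13, chromosome 9, 6720863 to 7175648) had 5.93 TPM (95% counting interval 5.64 to 6.23) and 5.25 TPM (4.99 to 5.53). KDM4D stood at 0.684 and 0.798 TPM, and KDM4E had no reads, for which the floor of 3 reads is 0.0484 TPM in either library. KDM4A was 3.03-fold and KDM4B 3.11-fold above KDM4C (log2 ratios of KDM4C to KDM4A -1.60 ± 0.033 and of KDM4B to KDM4C 1.64 ± 0.031). KDM4C exceeded KDM4D 7.55-fold (log2 ratio 2.92 ± 0.28). In CPM, KDM4A was 1.52-fold and KDM4B 2.94-fold above KDM4C, and KDM4C 26.2-fold above KDM4D. KDM4B and KDM4A differed by less than the replicate spread in TPM (log2 ratio 0.035 ± 0.0019), but by 0.95 in CPM, where its summed exon length of 9743 bases, against 5172 for KDM4A, is not divided out.

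Across the 23 histone lysine demethylases, 21 were detected, with a median of 11.4 ± 1.26 TPM at percentile 99.15 of random lists. The others were KDM4E and RIOX1, whose 0 and 2 reads are uncertain because other rows share 98.6% of its exon bases. The H3 lysine 4 demethylase KDM5B was highest with 61.1 ± 7.72 TPM, followed by KDM1A with 34.8 ± 1.96 and KDM5C with 33.6 ± 3.72 TPM. KDM5B exceeded KDM5A 5.35-fold (log2 ratio 2.42 ± 0.023), and the H3 lysine 27 demethylase KDM6A exceeded KDM6B 11.6-fold (3.54 ± 0.21). The KDM1A to KDM1B ratio of 1.31 (log2 0.39 ± 0.047) lay just above the replicate spread, and from replicate 1 alone, at 0.35 on the log2 scale, it did not pass.

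Writers and readers of H3 lysine 9 methylation were mostly present. Of 15 measured members 13 were detected, and the median was 16.5 ± 1.41 TPM at percentile 99.65. The heterochromatin proteins CBX3, CBX5 and CBX1 had 144 ± 24.2, 97.7 ± 14.7 and 94.4 ± 12.3 TPM. CBX3 was 1.47-fold above CBX5 in TPM (log2 ratio 0.56 ± 0.025), but in CPM the order turned, with a log2 ratio of -0.87, since CBX5 has 12508 exon bases against 4641 for CBX3. Among the methyltransferases, SUV39H2 exceeded SUV39H1 1.48-fold (log2 ratio of SUV39H1 to SUV39H2 -0.56 ± 0.024). Other rows cover 20.3% of the exon bases of SUV39H1 and 4.46% of those of SUV39H2. SUV39H1 may thus be underestimated, and this small ratio is uncertain. EHMT2 had no reads in either library, against 12.4 ± 1.06 TPM for its partner EHMT1. EHMT2 and DAXX (4 and 7 reads), the members not detected, lie in a block of chromosome 6 in which nearly all genes lacked reads, described below, so their values were not read as low expression.

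Of 17 histone methyltransferase and Polycomb genes 15 were detected, and their median of 9.82 ± 1.5 TPM lay at percentile 96.22 of random lists, below the upper bound of 97.5. With CPM in place of TPM it lay at 100. SUZ12, a core subunit of Polycomb complex PRC2, led with 32.5 ± 6.93 TPM, followed by ASH1L with 28.1 ± 2.11 and NSD1 with 27 ± 2.67 TPM. The catalytic subunit EZH2 stood 3.15-fold above EZH1 in TPM (log2 ratio 1.65 ± 0.12) and 2.03-fold in CPM. RING1, which had no reads, lies in the chromosome 6 block, and KMT2B, also without reads, shares 99.99% of its exon bases with other rows of the table, so its reads could not be assigned.

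Genes of chromatin architecture, the subject of the series, were expressed as a group. Of 26 members 24 were detected, and the median was 33.3 ± 6.0 TPM at percentile 100 of random lists. The nuclear lamin LMNA with 114 ± 6.26, HMGB2 with 105 ± 3.2 and the cohesin subunit RAD21 (ENSG00000164754.8, chromosome 8, 117858174 to 117887105) with 87.5 ± 18.8 TPM were highest. CTCF (ENSG00000102974.10, chromosome 16, 67596310 to 67673086), the insulator protein that bounds chromatin loops, had 32.6 ± 6.38 TPM, and its germline paralog CTCFL had no reads. The lower 95% counting bounds of the ratio of CTCF to CTCFL were 2375 in replicate 1 and 1798 in replicate 2. Mates of a pair counted one by one would make these bounds too high. The cohesin gene SMC1A exceeded the meiotic form SMC1B 105-fold in TPM (log2 ratio 6.71 ± 0.059) and 263-fold in CPM. The alternative cohesin subunits STAG2 and STAG1 stood at 20.1 ± 3.37 and 19.4 ± 2.97 TPM and differed by less than the replicate spread (log2 ratio 0.044 ± 0.023). PDS5A was 3.24-fold above PDS5B (log2 ratio 1.70 ± 0.029). LMNA was 1.53-fold above LMNB1 in TPM (0.62 ± 0.07) and 2.95-fold in CPM.

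Estrogen receptor coregulators were detected without exception, 18 of 18. Their median was 10.1 ± 0.538 TPM at percentile 97.45, just below the upper bound of 97.5 (97.2 from replicate 1 and 97.8 from replicate 2 alone, and 99.98 with CPM). The deacetylase HDAC1 with 63.7 ± 6.37, the arginine methyltransferase PRMT1 with 39.9 ± 3.01 and the coactivator NCOA3 with 32.1 ± 4.63 TPM led the list. NCOA3 exceeded NCOA1 3.77-fold (log2 ratio 1.92 ± 0.045) and HDAC1 exceeded HDAC2 7.13-fold (2.83 ± 0.0076), but in CPM only 1.85-fold. The acetyltransferase EP300 was 1.67-fold above CREBBP in TPM (log2 ratio 0.74 ± 0.021), but in CPM the log2 ratio was 0.086 and the call ended.

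Of 15 growth factor receptor genes 11 were detected, with a median of 2.96 ± 0.318 TPM at percentile 57.26. IGF2R was highest with 30.9 ± 2.67 TPM, followed by FGFR3 with 17.8 ± 1.02 and ERBB4 with 15.4 ± 1.3 TPM. ERBB2 and ERBB4 differed by less than the replicate spread in TPM (log2 ratio -0.016 ± 0.21). In CPM the log2 ratio was -0.35, larger than that spread. DDR1, with 1 and 2 reads, lies in the chromosome 6 block, and without genes of that block the list lay at percentile 68.95. The antiapoptotic gene BCL2 stood 44.8-fold below BCL2L1 in TPM (log2 ratio -5.49 ± 0.0067) and 19.4-fold below it in CPM.

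**Figure D2:**
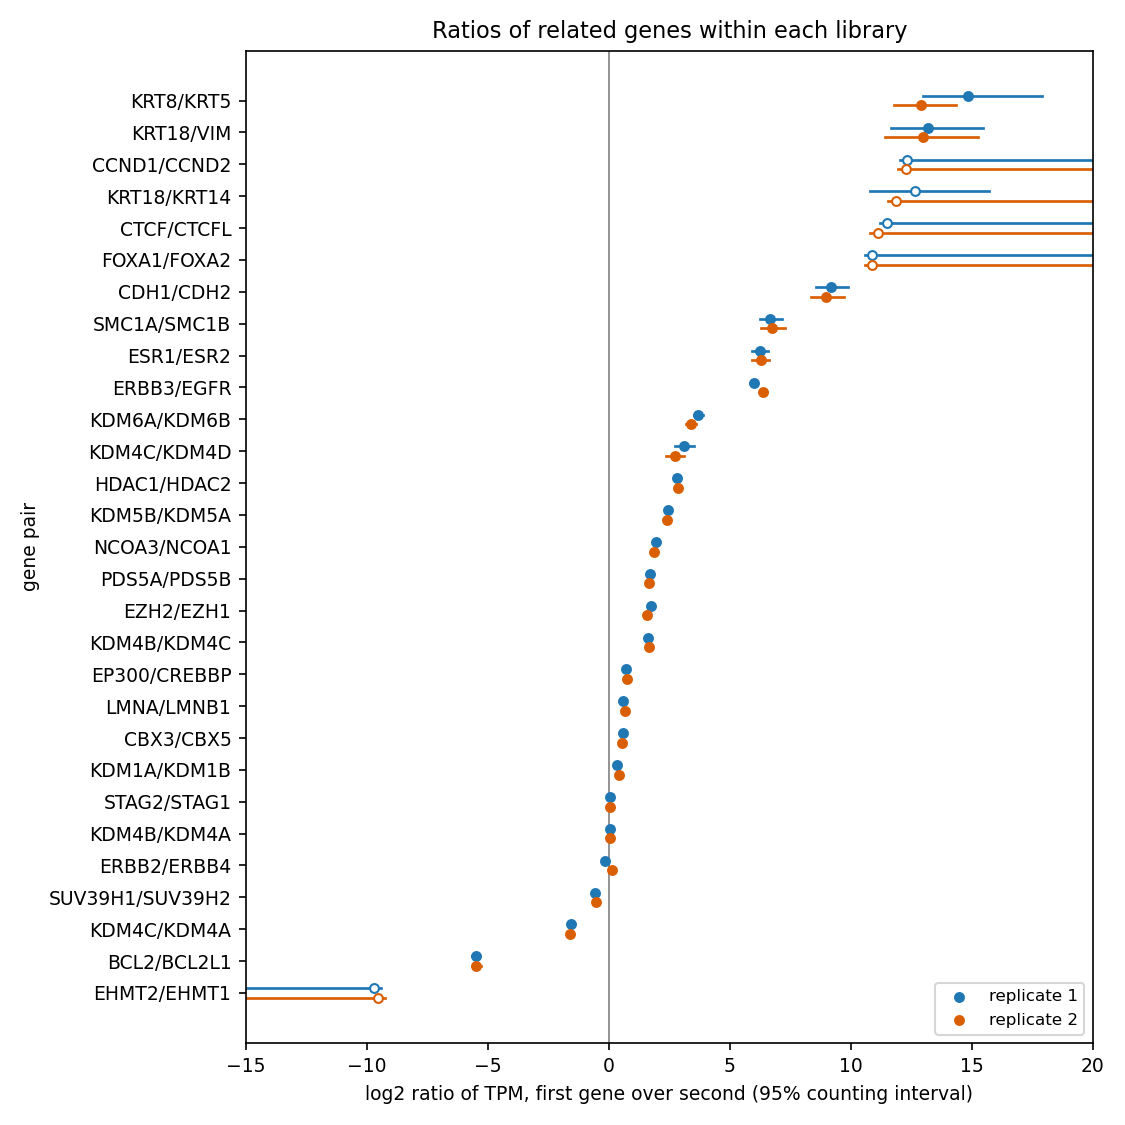
Ratios of 29 gene pairs on a log2 scale of TPM (x axis), with 1 point per library (blue for replicate 1, orange for replicate 2) and lines for exact 95% counting intervals; open points are pairs with 0 reads for 1 gene in at least 1 library, set at the floor of 3 reads. For 26 pairs the ratio was larger than the replicate spread, and for STAG2/STAG1, KDM4B/KDM4A and ERBB2/ERBB4 it was not. That spread is of the same gene between the libraries and holds no error between genes. In CPM, 14 of the 29 ratios moved by over 1.5 times. EHMT2 lies in the chromosome 6 block, so its ratio to EHMT1 is not read as a ratio of expression.

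Levels of proliferation and sterol synthesis transcripts lay above those of random lists of protein-coding genes. All 26 cell cycle genes were detected, with a median of 51.5 ± 6.13 TPM at percentile 100, led by the replication clamp PCNA with 262 ± 40.1, TOP2A with 209 ± 40.8 and CCNB1 with 195 ± 24 TPM. The 12 measured replication-dependent histone genes had a median of 607 ± 39.6 TPM, also at percentile 100. All 17 cholesterol synthesis genes were detected, with a median of 37 ± 8.68 TPM at percentile 100. FDFT1 with 102 ± 16.5 and IDI1 with 76.7 ± 21.7 TPM were among its highest members. Of 16 stress and unfolded protein response genes 13 were detected, with a median of 26.5 ± 4.84 TPM at percentile 99.98, and the reticulum chaperones CALR (417 ± 35.6), HSP90B1 (266 ± 23.9) and HSPA5 (257 ± 2.7 TPM) were highest. The heat-shock genes HSPA1A and HSPA1B had no reads and lie in the chromosome 6 block; without genes of that block the list lay at percentile 100.

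Interferon response genes were of middling level. Of 24 members 17 were detected, and the median was 1.06 ± 0.336 TPM at percentile 27.09 of random lists. BST2 with 135 ± 7.52 and IFI6 with 11.8 ± 3.36 TPM were among the highest, and IFNB1 and CXCL10 had no reads. The list was higher in replicate 2 in 17 of its 18 members at 1 CPM or more on average, and the cholesterol synthesis list was lower there in 16 of 17.

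Reference groups gave the scale of the libraries. All 15 housekeeping genes were detected, with a median of 204 ± 15.4 TPM, led by ACTB, EEF1A1 (893 ± 57.4) and RPLP0 (642 ± 37.8 TPM). The 13 mitochondrially encoded protein genes had a median of 599 ± 33.4 TPM, with MT-CO2 at 3045 ± 203, MT-CO1 at 2693 ± 206 and MT-CO3 at 2217 ± 3.39 TPM. Reads on the mitochondrial chromosome were 0.899% and 1.09% of the 2 libraries. The 8 structural noncoding RNAs matched by symbol were all detected, with a median of 71.4 ± 1.54 TPM. They leave out the 7SK RNA, counted under another name, with 814703 and 885024 reads in replicates 1 and 2. RN7SL1, RN7SL2 and RPPH1 were not matched by symbol either and may stand among the abundant rows. The median thus describes the 8 matched RNAs alone. RMRP had 56288 ± 451, MALAT1 2714 ± 256 and the telomerase RNA TERC 491 ± 22.2 TPM. These 3 lists lay at percentile 100 of random lists, which were drawn from protein-coding genes for the noncoding list too.

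A block of chromosome 6 that holds the major histocompatibility complex was nearly empty of reads. Between 28493702 and 33425325 (hg19), 160 of 177 protein-coding genes (90.4%) had at most 3 reads in each library, 138 of them none, against 23 of 133 genes (17.3%) in the flanks of about 5 Mb. The ribosomal protein gene RPS18 had 1 read in replicate 1 and 0 in replicate 2, while the other 80 cytosolic ribosomal protein genes had a median of 36464 reads over both libraries. HLA-B with 459 and 460 reads, HLA-DRB1 with 137 and 160 and AGPAT1 with 71 and 64 were among the 17 exceptions. A low value in this block is therefore not read as low expression here. RPS18 and the exceptions were chosen after their values were seen.

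**Figure D3:**
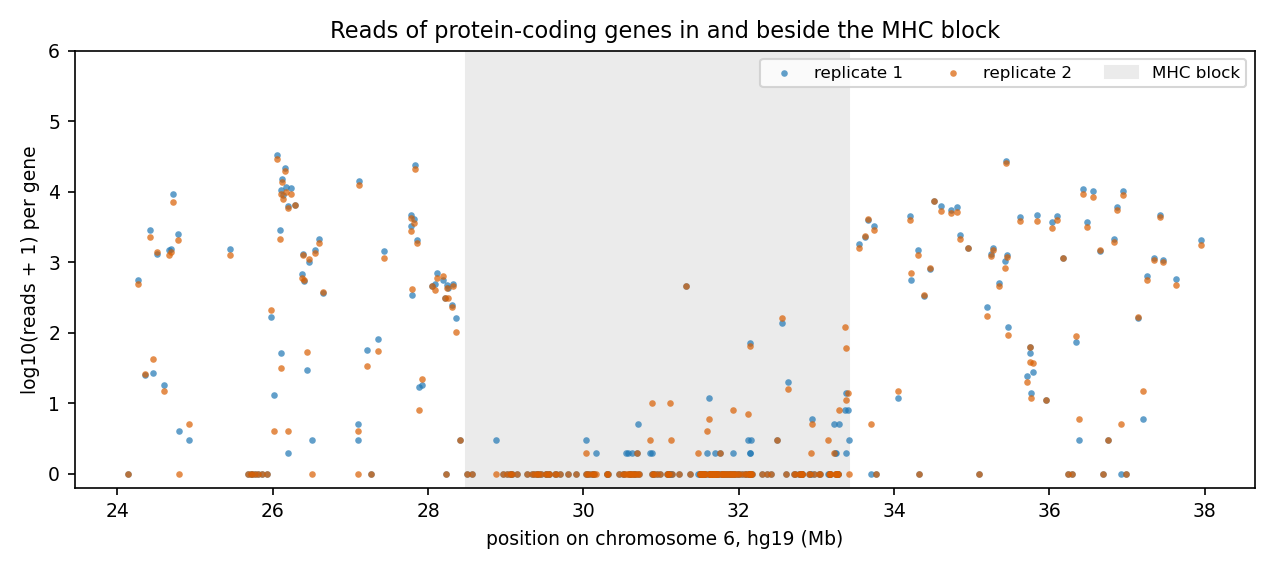
Reads per protein-coding gene, as log10(reads + 1), by position on chromosome 6 (hg19, Mb), with 1 point per gene and library and the block in grey. In the block 160 of 177 genes have at most 3 reads in each library, against 23 of 133 in the flanks.

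The 2 libraries were compared to set the error of all levels above. Across the 14668 genes at 1 CPM or more on average, log2(CPM + 1) correlated with Pearson's r = 0.995 and Spearman's rho = 0.994; genes are not independent replicates, so no p-value is given. The median absolute log2 difference was 0.25 for genes of 1 to 10 CPM, 0.12 for 10 to 100 CPM and 0.08 above 100 CPM, and its 95th percentile was 0.84, 0.36 and 0.28 in these classes and 3.35 below 1 CPM. The coefficient of biological variation estimated with edgeR was 9.61%. In an exact binomial test with Benjamini-Hochberg adjustment, which compares these 2 libraries and not conditions, 5823 genes (39.7%) differed at an adjusted p of 0.05, and 144 of them by 2-fold or more. With counts halved, an alternative chosen after seeing the data, 3094 genes differed.

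The differences between the libraries involved named genes of several groups. TFF1 was 2.21-fold and TMPRSS3 1.86-fold higher in replicate 2. The interferon-induced GTPase gene MX1 was 2.09-fold, the spliceosomal RNA RNU4-2 2.21-fold and the protease gene ADAMTS15 1.81-fold higher in replicate 2. Higher in replicate 1 were the Polycomb gene BMI1 (2.07-fold), EIF3C (3.26-fold), the pseudogenes KRT8P3 (5.09-fold) and RN7SL5P (1.9-fold), and a gene known here by its identifier alone, ENSG00000232561 (7.91-fold). EIF3C, KRT8P3, RN7SL5P and RNU4-2 have near-identical copies in the genome, so their reads are uncertain. Whether ENSG00000232561 has such copies was not examined, and other rows share 23.3% of the exon bases of BMI1. These 10 genes had the largest differences among those at 10 CPM or more on average. An adjusted p under 0.05 in the exact binomial test was part of the rule that selected them. Each kept one with counts halved, which uses the same reads and is no independent support. That test sets the libraries against counting error alone.

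**Figure D4:**
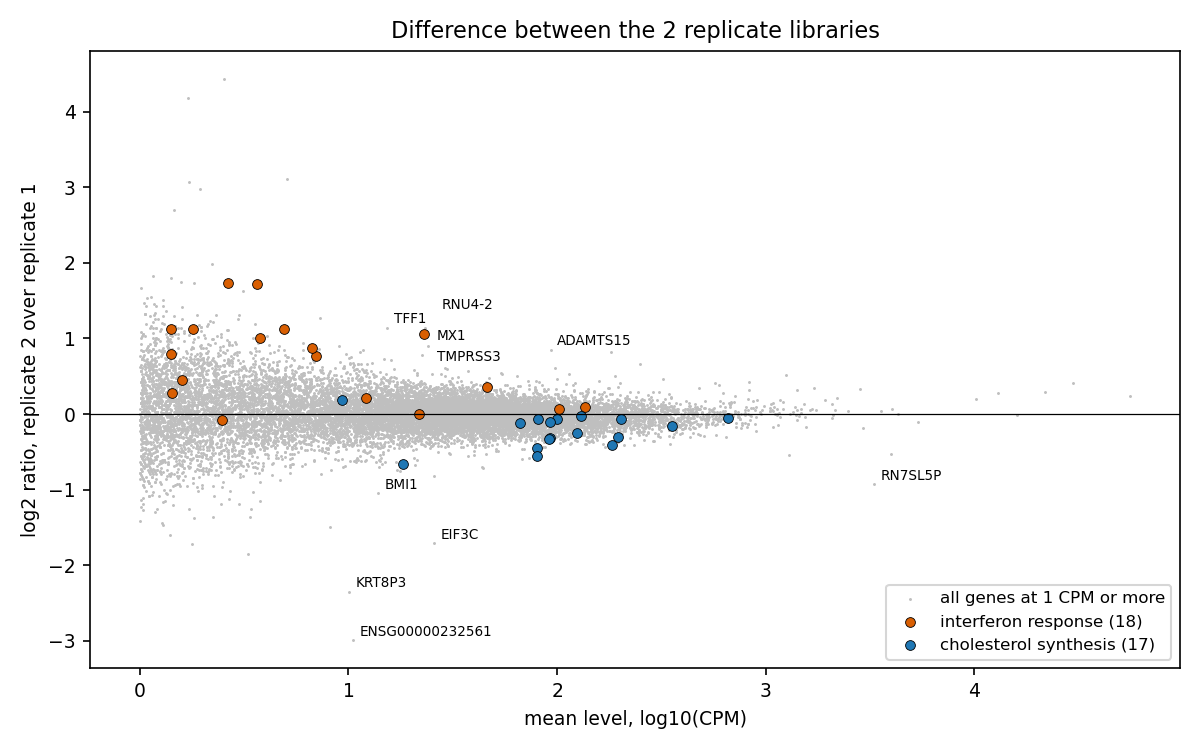
Log2 ratio of replicate 2 over replicate 1 (y axis) against mean level as log10(CPM) (x axis) for the 14668 genes at 1 CPM or more on average (grey), with the tested interferon response genes (orange, 18) and cholesterol synthesis genes (blue, 17). Of the interferon genes 17 lie above 0, and of the cholesterol synthesis genes 16 lie below it.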

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

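Of 295 values of 76 main results under alternative settings, 276 kept their side of the threshold or stayed within the set tolerance. That number scores list medians by percentile alone and leaves out the printed levels, which depend on the scale. With TPM over nuclear protein-coding genes, the levels of 128 named genes moved beyond tolerance and those of 5 did not. With CPM, the median log2 level moved for 20 lists and stayed for 1. The 2 settings with halved counts and without the chromosome 6 block were chosen after seeing the data. Counts of detected genes ran from 10750 at 5 CPM to 16259 at 0.5 CPM, and Pearson's r from 0.992 to 0.997. With counts halved 3094 genes differed between the libraries in place of 5823, and with all genes of at least 1 read 1110 in place of 144 differed by 2-fold or more, where genes of few reads enter. At 5 CPM 5 basal, 1 mesenchymal, 0 immune, 0 endothelial and 7 interferon genes were detected, and at 0.5 CPM 4 mesenchymal and 2 endothelial genes. With CPM in place of TPM, the immune list moved to percentile 2.90 and lost its place below random lists, while the Polycomb and methyltransferase list (100) and the coregulators (99.98) rose above them. Single libraries gave percentiles of 2.20 to 4.56 for the immune list and 97.2 to 97.8 for the coregulators, and log2 ratios of 0.35 to 0.42 for KDM1A/KDM1B, of which the lower lost the call. In CPM the log2 ratio of CBX3 to CBX5 turned to -0.87, that of EP300 to CREBBP fell to 0.086 and lost its call, and those of ERBB2 to ERBB4 (-0.35) and KDM4B to KDM4A (0.95) gained one; CPM leaves out gene length, which is the whole of that change. Of the 29 pairs drawn, 14 moved by over 1.5 times in CPM. Those not yet named were, in log2 ratios, KDM4C/KDM4A (-0.60), KDM4C/KDM4D (4.71), HDAC1/HDAC2 (0.89), EZH2/EZH1 (1.02), SMC1A/SMC1B (8.04), CTCF/CTCFL (10.3), LMNA/LMNB1 (1.56), BCL2/BCL2L1 (-4.28), KRT18/VIM (12.5), FOXA1/FOXA2 (11.5) and EHMT2/EHMT1 (-10.7). Without genes of the chromosome 6 block, median log2(TPM + 0.1) rose from 4.68 to 5.16 for the stress list and from 1.61 to 2.04 for growth factor receptors, and from 4.08 to 4.10 and 3.30 to 3.39 for the heterochromatin and Polycomb lists. Leaving out a replicate gives no replicate correlation and no test of differing genes. For lists with fewer than 3 detected members no median of detected members was taken, and the other deposited table holds none of these libraries. No paired analysis was possible because there was 1 group. Depth limits genes near 3 reads per library, where a ratio rests on a few reads.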

Other observations

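The tests of the chromosome 6 block and of the excess of even read counts were chosen after the results were seen. The replicate libraries differed by gene group and in composition. In replicates 1 and 2, 82.4% and 80.1% of reads lay on protein-coding genes, 0.899% and 1.09% on the mitochondrial chromosome, 0.124% and 0.177% on mitochondrial ribosomal RNA, and 15.4% and 17.5% on the 10 most abundant genes. Of 18 tested interferon response genes 17 were higher in replicate 2, with a median log2 difference of 0.78, against -0.13 to 0.19 for the middle 95% of 10000 random lists matched on expression. The ubiquitin-like modifier ISG15 had 51 and 151 reads, and IFIT1, which binds foreign RNA, 71 and 207. Sterol synthesis genes went the other way: 16 of 17 were lower in replicate 2, with a median of -0.15 at percentile 0.09. STARD4, a sterol transfer protein, was 1.58-fold and SC5D 1.47-fold lower. Chromatin architecture genes were lower in 20 of 24 cases (median -0.14, percentile 0). Estrogen response genes were higher in 19 of 30 (median 0.11, percentile 99.98), among them TFF3 (1.76-fold), IGFBP4 (1.33-fold) and STC2 (1.3-fold). The other 11 were lower in replicate 2, among them PKIB (1.2-fold), CXCL12 (1.17-fold) and MYBL1 (1.13-fold), while PGR differed by only -0.01 on the log2 scale. TFF3, TFF1 and TMPRSS3 all lie on chromosome 21 between 43731777 and 43816955 (hg19). Removal of the median difference of genes of like length and GC content reduced the median of chromatin architecture genes to -0.08 (percentile 0.18). That of cholesterol synthesis became -0.21 (percentile 0) and that of estrogen response 0.13 (percentile 100). Cell cycle genes were lower in replicate 2 in 20 of 26 cases, at percentile 5.22 before this removal and 0.51 after it, and replication-dependent histones moved from percentile 70.75 to 1.26.

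The interferon difference between the libraries was not accounted for by 2 technical explanations that were tested. After removal of the median difference of genes of like length and GC content, the list's median was still at the 100th percentile of random lists. With counts halved, 55.6% of the 18 tested genes (10) kept an adjusted p under 0.05 in the exact binomial test. Over all genes of this comparison, 3094 of 14668 did so. Both are more than counting noise alone would give, so passing this test is not particular to the interferon genes. No biological explanation was tested, since the design has 1 group; a response of 1 culture to transfected RNA, a batch, or the source of the different composition may lie behind it, and all of these stay open.

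The nearly empty block of chromosome 6 may be a loss of reads at alignment or counting. RPS18, whose protein is part of the ribosome, had 0.00274% of the median reads of the other ribosomal protein genes, which a dividing cell would not be expected to survive. Further copies of the block in the alignment reference are a candidate explanation, since the counter by default leaves out reads that fit several copies. In a region of chromosome 17 that also has an alternate haplotype in hg19, 21.4% of 14 protein-coding genes had at most 3 reads, against 19.7% of 71 in its flanks. The region holds few genes, and whether the reference carried such copies is not given in the sources used here, so this stays undecided. No biological explanation was tested.

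More genes had exactly 2 reads than exactly 1, by a factor of 1.64 in replicate 1 and 1.57 in replicate 2, and more had 4 than 3. Counts of single molecules would fall steadily from 1 read upward, and mates of a read pair counted as 2 reads could give this excess of even counts. The counting intervals in the report would then be too narrow. With counts halved, 3094 in place of 5823 genes differed between the libraries. No biological explanation was tested.

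Several of the widest gaps between the libraries lay on rows with near-identical copies or in the chromosome 6 block; the examples were chosen after their values were seen. MTX1P1, a pseudogene, had 44 and 339 reads, KIFC1 had 7 and 120, PHF1 had 1 and 60 and GSTT2B had 113 and 30 in replicates 1 and 2. The most abundant rows of the table were 2 short genes on chromosome 14 known here by identifier alone, ENSG00000258486 with 5.59% ± 0.60 (SD, n = 2) and ENSG00000265150 with 2.99% ± 0.56 of all reads, and the 7SK RNA with 2.17% ± 0.29.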
